A study of Mus musculus with 50 samples.

How the data were processed

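Dorsal root ganglia of naive mice of 25 inbred strains were profiled, with 1 Affymetrix mouse expression array of 45101 probe sets for each sex of each strain, 50 arrays in all. Per the labels' protocols, the mice were 2 months old, each array carried total RNA pooled from 3 mice, and the target was labelled with biotin. Strain names are given below exactly as the labels spell them.

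The deposited values are linear intensities, 1 per probe set and array, which the authors made with GCRMA (background correction and normalization of the probe signals) in R 2.6.2, per the submitters' processing notes. No further setting of that step is recorded. The values ran from 1.63 to 36604 and were not log-transformed, so that all analysis here was done on the log2 of the value + 1. The plan written before the files were opened had assumed log2 values and foresaw this transformation for a linear file. The 25 male arrays had their lowest intensity between 1.629 and 1.655 and the 25 female arrays between 1.726 and 1.744, and array means ran from 192.6 to 202.0 in males and from 201.6 to 209.6 in females. The ranges of the lowest values do not overlap, and the arrays of the sexes look as if they had been normalized as separate sets. No label records this.

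Control probe sets (64) were left out. Of the other 45037 probe sets, 34945 carried exactly 1 gene symbol, 932 carried more than 1 and 9160 carried none in the table of probe genes. Of the probe sets with 1 symbol, 34741 matched a gene identifier in the RefSeq gene table (assembly GRCm38.p6), which was used for names and for the order of neighbouring genes only, and 0 symbols needed an update. A probe set was tested when its log2 intensity was above 4 in at least 2 arrays, which kept 22205 probe sets. For statements on genes, the probe set with exactly 1 symbol and the highest mean over all arrays stood for the gene, which gave 11204 tested genes of 18193 named.

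Strain and sex were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). The strain test was the moderated F test over 25 strain means with sex as an additive term, so that the male and the female pool of a strain served as its 2 replicates. The sex test compared males with females with strain as a block, since every strain gave 1 pool of each sex. Each strain was also compared with the mean of the other 24, with a difference of at least 1 log2 unit required. P-values were adjusted by the Benjamini-Hochberg method over all probe sets tested, and for the single strains over all probe sets and strains together. A result was called at an adjusted p under 0.05.

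For Chrna6, strain means of the male and the female value were correlated with those of the 10 other nicotinic and P2X subunits tested, by Pearson's r and Spearman's rho with two-sided permutation tests of 100000 resamples. The smallest p that these permutations can give is 1e-05. A limma fit with the Chrna6 strain mean as covariate searched all 22203 other probe sets tested. Before the data were examined, 37 gene lists were fixed: receptor, channel and signalling genes, markers of neuron types, glia, blood, vessels and adjacent tissues, immune and stress genes, sex chromosome genes, known strain variants and genome neighbours of Chrna6. Each list was tested for sex with camera (preset inter-gene correlation of 0.01, and an estimated correlation as the alternative). For strain, the list means of the male and female arrays were correlated over strains, and the share of called members was compared with all other genes by Fisher's exact test. Arrays were compared by Pearson's r over all probe sets tested, after the mean of each sex was subtracted. For the lists and for the male and female values of Chrna6, rho and r without the 2 strains farthest from the median were added after the values of r had been seen. A correlation of arrays is across probe sets, which are not independent replicates.

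Named genes follow a rule fixed before the data were examined. Chrna6, Chrnb3, P2rx2 and P2rx3 are always named. For strain, the rule takes the 15 called genes with the largest range of strain means and a male to female correlation above 0.8, the known strain variants, and up to 3 called members of each list by range. For sex it takes the 10 called genes with the largest change in each direction, and as many again without the sex chromosome genes where at least 20 of the 25 strains share the sign. For single strains it takes the 3 largest rises and falls in each of the 5 strains with the most calls and in c57BL/6J. Genes named outside this rule are marked as chosen after their values were seen.

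The tests were tried on simulated data, with 200 changed probe sets of 22205. Values were drawn independently for each probe set from a normal distribution with its real mean and residual SD. Related genes and outlying arrays were therefore not simulated, and each strain change was placed in 1 strain. The strain test called 0% of simulated differences of 0.5 log2 units, 13.4% at 1 and 74.2% at 2, and 7.9% of its calls were false. The comparison of single strains called 0%, 37.3% and 97.0% at these sizes. Its 0% at 0.5 follows largely from the required difference of 1 log2 unit. The adjusted threshold depends on the number of calls, 63 in the simulated strain test against 5475 in the data. These shares therefore do not carry over to the real strain test. The sex test called 23.9% at 0.2 log2 units, 92.5% at 0.5 and 100% at 1, with 4.6% of its calls false. The covariate fit called 100% of 200 simulated genes, with 3.4% of its calls false. The correlation test recovered 100% of 20 simulated relations and called 1 other gene. Only strong relations were simulated for the covariate fit and the correlation test, so these figures do not show how often weaker relations are missed. The number of arrays, 2 per strain, limits the precision of every strain value.

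Alternatives fixed before the data were examined changed the filter, the array scaling, the variance model, the choice of probe sets, the constant added before the log, the sex term or strain block, and left out each array or strain in turn. Chosen after seeing the data were 3 sets of arrays left out (the strains SM/J and PL/J, the 2 arrays with the highest Gapdh 3' to 5' signal, and both together), the split of strains into the 6 with the highest Chrna6 and the others, and the comparison of arrays by 136 strain markers with 2 clear states (F above 40 and variance above 0.5). For that comparison the markers came from the 18 strains whose arrays were each other's closest. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 served for correlations and permutations. Pain phenotypes and genotypes of the strains were not used here.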

Results

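The data are 50 arrays of dorsal root ganglion, the ganglion that holds the cell bodies of the body's sensory neurons, from 25 inbred mouse strains with 1 pool of 3 males and 1 pool of 3 females each. Every strain value below is the mean of these 2 arrays, and the male and female pools are the only replicates of a strain. Arrays had 18738 to 19365 probe sets above a log2 intensity of 4 and array medians of 9.43 to 10.53 in linear units. All values and changes are log2 intensities.

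Chrna6, which encodes the alpha6 subunit of nicotinic acetylcholine receptors and which the series title names, differed between strains. Its leading probe set was highest in C3H/HeJ at 9.49 ± 0.06 (SD, n = 2), followed by NZO/HILtJ at 9.18 ± 0.05, DBA/2J at 9.09 ± 0.06, NZW/LacJ at 9.08 ± 0.04, AKR/J at 8.99 ± 0.35 and RIIIS/J at 8.59 ± 0.16. KK/HIJ at 6.53 ± 0.06 and PL/J at 6.28 ± 2.11 had the lowest means, and c57BL/6J lay at 7.46 ± 0.04. The range of strain means was 3.22 (limma F test, adjusted p = 0.000645). The sexes did not differ on average (0.14 higher in males, SE 0.17, adjusted p = 0.491).

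Male and female Chrna6 values correlated over the 25 strains (r = 0.62, permutation p = 0.00051; rho = 0.61, p = 0.00149; r = 0.71 without SM/J and C3H/HeJ, the farthest from the median). The pools of 2 strains disagreed: SM/J had 9.67 in the male and 6.84 in the female array, and PL/J had 7.77 in the male and 4.79 in the female array. The arrays labelled male PL/J and female SM/J also carried transcripts of both sexes, with Xist, the RNA that silences an X chromosome, at 8.97 and 9.43, and Eif2s3y, a Y chromosome gene, at 6.52 and 6.82; the Y chromosome gene Kdm5d was at 3.82 in the first and at 2.67, the female level, in the second. Without SM/J and PL/J, left out after seeing the data, the range was 2.96 (adjusted p = 9.7e-11) and the male to female correlation 0.93 (permutation p = 1e-05, n = 23). The second Chrna6 probe set had a range of 5.29 (adjusted p = 0.00383), a male to female r of 0.54 (permutation p = 0.0052) and strain means that correlated at 0.93 with those of the first (permutation p = 1e-05). It lay below 4 in the male PL/J (3.48), female P/J (3.77), male BTBT T+tf/J (3.79), female SM/J (3.89) and female PL/J (3.94) arrays. Of these, the P/J and BTBT T+tf/J arrays had the highest 3' minus 5' signal of the control gene Gapdh (0.34 and 0.60), and the other 3 arrays had -0.31, -0.54 and -0.35.

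**Figure D1:**
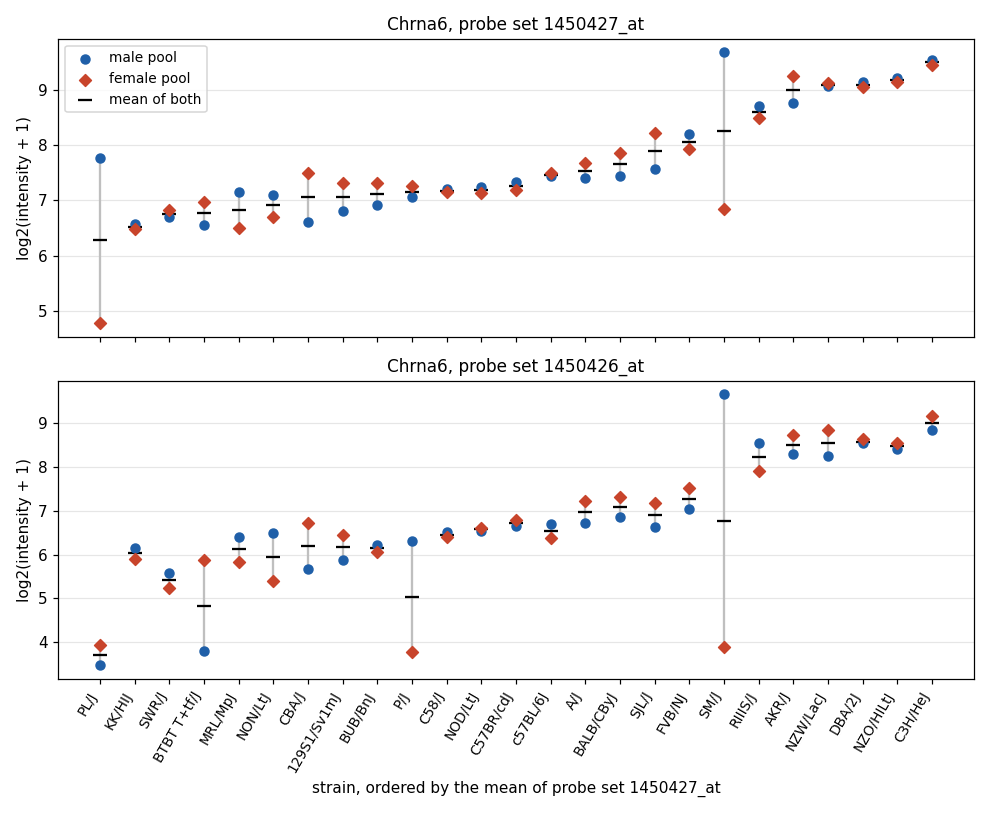
Log2 intensity of both Chrna6 probe sets in the male pool (circle) and the female pool (diamond) of each strain, with the mean of both as a bar and strains ordered by the mean of the leading one. C3H/HeJ has the highest mean at 9.49, and the pools of SM/J (9.67 and 6.84) and PL/J (7.77 and 4.79) lie far apart.

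The series title also names P2X2/3 receptors, the ATP-gated channels of nociceptive neurons. P2rx3, whose product forms these channels alone or with P2X2, was abundant in every strain at a mean of 11.39 and ranged by 0.90 between SJL/J at 11.76 and C57BR/cdJ at 10.86 (adjusted p = 0.00128); a further probe set of P2rx3 followed these strain means weakly (r = 0.22). P2rx2 lay near the floor with a mean of 3.36, above 4 in 3 of 50 arrays, and was not called for strain (range 0.77, adjusted p = 0.76). Chrnb3, which encodes the beta3 subunit and lies close to Chrna6 in the genome, had a mean of 2.51 and did not pass the filter. Of 5 tested nicotinic subunits, 3 were called for strain: Chrna6, Chrna3 with a range of 2.48 between BTBT T+tf/J and 129S1/Sv1mJ, and Chrna7 with 1.91 between RIIIS/J and DBA/2J (3 adjusted over the list alone). Of 6 tested P2X genes, P2rx3 and P2rx4, the latter with a range of 0.63, were called (2 adjusted over the list alone). A further probe set of P2rx4 followed the leading one weakly (r = 0.25) and was not called (limma F test, adjusted p = 0.105). That of Chrna3 followed at r = 0.75 with a range of 0.94 and was not called either (adjusted p = 0.602).

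Over strain means, Chrna6 correlated with P2rx2 (r = 0.59, permutation p = 0.0019, adjusted p = 0.019 over 10 receptor genes; rho = 0.46, p = 0.0228). Without C3H/HeJ and NZO/HILtJ, the farthest from the median of Chrna6, r was 0.49 (p = 0.0172). It was 0.55 in female arrays (adjusted p = 0.0473) and 0.15 in male arrays (adjusted p = 0.7), and 0.79 within the 6 strains with the highest Chrna6 (permutation p = 0.025) and 0.37 within the other 19 (permutation p = 0.115). The call was lost without NZW/LacJ (r = 0.53, adjusted p = 0.0742), without DBA/2J (0.53, adjusted p = 0.0729), without C3H/HeJ (0.48, adjusted p = 0.174) and with the second Chrna6 probe set (adjusted p = 0.0668). P2rx2 values of males and females did not correlate over strains (r = -0.25). For P2rx3, r with Chrna6 was 0.24 (permutation p = 0.24, adjusted p = 0.801; rho = 0.25, p = 0.222). The other 8 receptor genes, from Chrnb2 (r = 0.29) to Chrna3 (r = -0.14), were not called either (lowest adjusted p = 0.793).

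Of 22203 other probe sets, limma called 0 for a relation with Chrna6 over strains, with 1409 at an unadjusted p under 0.05. Of the 8 tested genes in the list of chromosome 8 neighbours, Chrna6 was the only one called for strain (1 adjusted over the list alone). Among 31 tested genes within 60 genes on either side of Chrna6, the same limma fit called 0 for a relation with it. An unadjusted p under 0.05 was found for 2: Erlin2, an endoplasmic reticulum membrane gene (r = -0.52, p = 0.0164), and Fgfr1, a fibroblast growth factor receptor (r = -0.45, p = 0.0222). Both had an adjusted p of 0.344 over the neighbours. Of the list, Hgsnat, Fnta and Hook3 lay within this window, so the list does not describe the region around Chrna6. Other genes in the window were called for strain by the limma F test: Dusp26 (adjusted p = 5.21e-05), Letm2 (0.000532), Tti2 (0.0179) and Kcnu1 (0.0186).

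Across strains, the signals of some genes ranged from the floor of the arrays to high levels in a strain pattern that males and females shared. Rpn1, a subunit of the oligosaccharyltransferase of the endoplasmic reticulum, had the widest range at 7.92: it lay at 3.34 in P/J and at a mean of 10.88 over the other strains. Ncmap, a gene of myelinating Schwann cells, lay at 2.85 in RIIIS/J and at 9.71 over the other strains. Ifi27l2a, an interferon-inducible gene, ranged by 7.16 from P/J at 3.08 to NZO/HILtJ at 10.25, and the MHC class I gene H2-K1 by 5.69 from AKR/J at 5.12 to BUB/BnJ at 10.81. The liver secretory genes Alb, Ttr and Serpina1c were highest in DBA/2J, at 8.88, 9.13 and 7.81.

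The moderated F test called 5475 of 22205 probe sets (24.7%), with 2929 of 11204 genes, and 4219 of these probe sets had strain means at least 1 log2 unit apart. Without the male P/J array the counts were 8304 and 6545. Without the strains SM/J and PL/J the first count was 5233, and without the 2 arrays with the highest Gapdh 3' to 5' signal it was 6375.

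Other genes with the widest ranges were Erdr1, an erythroid differentiation regulator, with 10.32 in BALB/CByJ and 3.33 in RIIIS/J, and the copine gene Cpne8 with a range of 6.72. In Cpne8, the strains AKR/J, BALB/CByJ, SJL/J, NZW/LacJ, BUB/BnJ, DBA/2J and MRL/MpJ lay below 4 in both arrays. Gdpd3, a phosphodiesterase gene, ranged by 6.49 and was highest in RIIIS/J at 10.02. Cap1, which binds actin and adenylyl cyclase, ranged by 6.16 and was lowest in AKR/J at 4.80. Stk25, a protein kinase gene, ranged by 5.92 from MRL/MpJ at 3.05 to SM/J at 8.97. The predicted gene Gm13306 ranged by 5.63, 5730409E04Rik by 5.60 with its lowest mean in NZW/LacJ at 3.67, and Rpgrip1, a gene of photoreceptor cilia, by 5.56 with its highest mean in C57BR/cdJ at 8.85. The male to female r of these 15 genes ran from 0.85 for Serpina1c to 0.98 for Gm13306, and their adjusted p was at most 7.45e-08. The naming rule required a strain call and an r above 0.8, so neither value is separate evidence. A further probe set of the gene followed the strain means of Rpn1 (r = 1), Cap1 (r = 0.99), Ttr (r = 0.99), Cpne8 (r = 0.97) and H2-K1 (r = 0.84); both probe sets of Rpn1 and the leading ones of Erdr1, Ttr and H2-K1 carry the suffix for probes that can bind related transcripts.

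**Figure D2:**
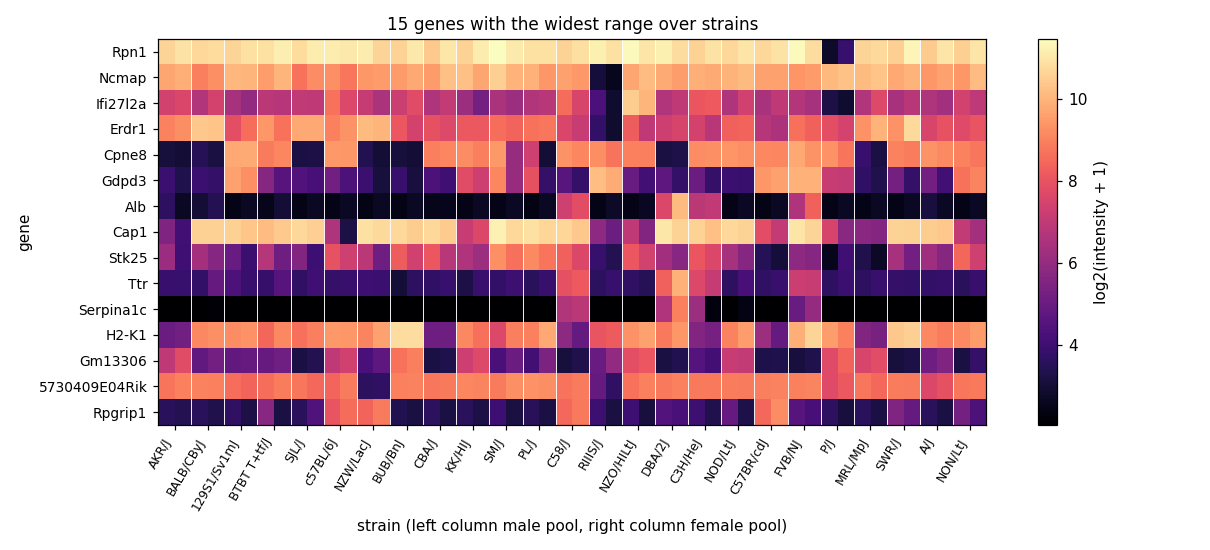
Log2 intensity of the 15 genes with the widest range of strain means, with 1 row per gene and the male (left) and female (right) pool of each strain side by side. Rpn1 is low in both pools of P/J (2.83 and 3.86) and Ncmap in both pools of RIIIS/J (3.08 and 2.61).

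Genes known to vary between inbred strains did so here. All 7 tested members of that list were called (7 adjusted over the list alone; Fisher's exact test against other genes, adjusted p = 0.00307). Pttg1, the separase inhibitor securin, was highest in c57BL/6J at 10.02 and had a range of 4.96. Alad, an enzyme of heme synthesis, ranged by 2.35 from c57BL/6J at 6.29 to SWR/J at 8.64. Glo1, a glyoxalase, ranged by 2.01 from FVB/NJ at 10.76 to BALB/CByJ at 12.77. Nnt, a mitochondrial transhydrogenase, ranged by 2.14 with its lowest mean in DBA/2J at 6.37, H2-Ea by 2.18 and Gpnmb, near the floor, by 2.10. Wdfy1 ranged by 2.77 and was lowest in c57BL/6J at 5.58, and its call was lost without the male c57BL/6J array (adjusted p = 0.0817).

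Markers of nociceptor types differed between strains. In the non-peptidergic list 6 of 8 tested members were called (6 adjusted over the list alone; Fisher's adjusted p = 0.0249), and in the peptidergic list 6 of 7 (6 over the list alone; 0.0097). Mrgpra3, an itch receptor gene in both the non-peptidergic and the itch list, ranged by 5.43 from SJL/J at 3.26 to RIIIS/J at 8.69. The angiotensin receptor gene Agtr1a ranged by 1.55 and the lysophosphatidic acid receptor gene Lpar3 by 1.33. Of the peptidergic genes, Gfra3, the artemin co-receptor, ranged by 2.07 from DBA/2J to SJL/J, and the capsaicin receptor gene Trpv1 by 1.27 from SWR/J at 7.50 to c57BL/6J at 8.77. Galanin (Gal), in the peptidergic and the nerve injury list, ranged by 2.56 with its highest mean in SJL/J, through the male array at 10.26 more than the female at 7.82, and its adjusted p of 0.04 passed 0.05 without any of 33 single arrays (0.0511 to 0.0625). List means correlated between males and females over strains in the first list (r = 0.70, rho = 0.62, r = 0.69 without the 2 farthest strains) and in the second (r = 0.72, 0.64 and 0.52). Mrgpra3 weighs on the first list, at -3.98 in SJL/J and -3.31 in NON/LtJ relative to the other strains. NON/LtJ had the lowest mean of that list (-0.61) and was kept in the r of 0.69. Neither this list nor the itch list was correlated without Mrgpra3.

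In the other neuron lists 40% to 66.7% of members were called, against 26.1% of all genes, and Fisher's exact test called none of them. The itch list had 4 of 7 called (5 adjusted over the list alone; adjusted p = 0.168), with neurotensin (Nts) ranging by 3.60 and somatostatin (Sst) by 3.20. The list of C low-threshold mechanoreceptors had 2 of 3 (2 over the list alone; 0.285), with tyrosine hydroxylase (Th) ranging by 2.81 from NZW/LacJ at 6.45 to P/J at 9.26, and Tafa4 by 0.96. The list of large-diameter neurons had 4 of 10 (6 over the list alone; 0.443), with the calcium-binding Calb1 ranging by 2.76 from NZW/LacJ to RIIIS/J, Tafa1 by 2.09 and the neurofilament gene Nefh by 0.95. Male and female means of these lists correlated at 0.71, 0.76 and 0.51 (rho 0.71, 0.74 and 0.46; without the 2 farthest strains 0.66, 0.72 and 0.68), all called.

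Ion channel genes varied as well. In the sodium channel list 6 of 9 members were called (6 adjusted over the list alone; Fisher's adjusted p = 0.0465), with the beta2 subunit gene Scn2b ranging by 2.48 from SJL/J to BTBT T+tf/J, Scn4b by 1.44, and Scn8a also called. In the list of TRP, ASIC and Piezo channels 6 of 9 were called (8 over the list alone; 0.0465). Asic3, an acid-sensing channel gene, ranged by 4.08 from CBA/J at 5.55 to BTBT T+tf/J at 9.62, the irritant receptor gene Trpa1 by 1.77 from BTBT T+tf/J to SJL/J, and Asic2 by 1.34. In the list of potassium and HCN channels 11 of 18 were called (14 over the list alone; 0.0097), with Kcnj3 ranging by 1.93, Kcns1 by 1.92 and Kcnc1 by 1.77. In the calcium channel list 4 of 11 were called (7 over the list alone; 0.651), with Cacna2d2, a subunit of the class that gabapentin binds, ranging by 2.26, the T-type channel gene Cacna1h by 1.93, and Cacna1c by 1.09. BTBT T+tf/J had the highest mean of the sodium, potassium and calcium lists; its male array had the highest Gapdh 3' minus 5' signal at 0.60, and without that array and the female P/J array Cacna1c was no longer called (adjusted p = 0.059).

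For these 4 channel lists, the male to female r of the list means was 0.59, 0.32, 0.45 and 0.41, with adjusted p of 0.0074, 0.176, 0.04 and 0.0658 and rho of 0.64, 0.35, 0.43 and 0.42. Without the 2 farthest strains, BTBT T+tf/J being 1 of them in each list, r was 0.58, 0.20, 0.27 and 0.23, so that for the potassium and HCN list the relation rests on those strains. Of opioid, cannabinoid and monoamine receptor genes 7 of 12 were called (10 adjusted over the list alone; Fisher's adjusted p = 0.0563), with the serotonin channel subunit Htr3b ranging by 2.61 and the serotonin receptor Htr1d by 1.86. Npy2r ranged by 2.04 and lost its call without any of 32 single arrays (adjusted p 0.05 to 0.111). Of GABA and glutamate receptor genes 5 of 14 were called (5 over the list alone; 0.538), with Gria1 ranging by 2.20 and Gabrb2 by 2.10; Gabra2, with 2.18, was not called without the male c57BL/6J array (adjusted p = 0.0753). Male to female r was 0.45 for the monoamine and opioid list (rho = 0.48) and 0.43 for the other (rho = 0.37, not called), and 0.36 and 0.34 without the 2 farthest strains, neither called.

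Signals of genes of antigen presentation and of the interferon response followed strain in both sexes. A strain variant under the probes, which changes binding and not the transcript, stays open as a source of these differences. In the MHC class I list 4 of 6 members were called (4 adjusted over the list alone; Fisher's adjusted p = 0.116) and list means correlated at 0.94 between the sexes (rho = 0.87, 0.93 without the 2 farthest strains); H2-D1 ranged by 4.74 from AKR/J to BUB/BnJ, and B2m, the class I light chain, by 1.42. In the MHC class II list 6 of 7 were called (6 over the list alone; 0.0097; r = 0.77, rho = 0.77, 0.76), with H2-Eb1 ranging by 4.88 from FVB/NJ at 3.14 to SJL/J at 8.03, and H2-Ab1 by 2.44. Of interferon-stimulated genes 9 of 11 were called (9 over the list alone; 0.00337; r = 0.82, rho = 0.73, 0.73). Ifit3, Ifit1 and Oasl2, antiviral genes, were all highest in c57BL/6J and ranged by 3.30, 2.89 and 2.89. In the macrophage list 5 of 10 were called (5 over the list alone; 0.247; r = 0.57, rho = 0.68, 0.60), with Aif1 ranging by 2.93 from DBA/2J to C57BR/cdJ. Cd163 ranged by 1.96 and was not called without the female NON/LtJ array (adjusted p = 0.097), and the complement gene C1qb ranged by 2.15 and was not called without any of 11 single arrays (0.05 to 0.0606).

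Each strain had genes that set it apart from the other 24, with 6335 calls over all strains. BTBT T+tf/J had the most with 609 (140 higher and 469 lower), then P/J with 418. Next came 129S1/Sv1mJ with 379, c57BL/6J with 322 and RIIIS/J with 269. SM/J had the fewest with 137, from 2 arrays that correlated at only 0.23. The array labelled female SM/J carries genes of both sexes. Few calls did not go with low agreement in general, since the arrays of P/J correlated at 0.14 and those of BTBT T+tf/J at 0.33. The male BTBT T+tf/J array and the female P/J array had a Gapdh 3' minus 5' signal of 0.60 and 0.34, the only ones above 0. That of actin, another control gene, was highest in the female P/J (2.62), male BTBT T+tf/J (2.61) and female c57BL/6J (2.59) arrays. Female 129S1/Sv1mJ followed at 2.19, against means of 1.464 in females and 1.429 in males, while RIIIS/J had 1.10 in the male and 1.12 in the female array. Whether RNA quality adds to the counts of single strains was not tested. In BTBT T+tf/J, Gm26782 was higher by 3.25, and Ly86, a partner of a toll-like receptor, was lower (-2.62), as were the ribosomal protein gene Rpl14 (-2.57) and the mitochondrial carrier gene Slc25a38 (-2.47). The keratin gene Krt8 (2.61) and the chemokine gene Cxcl2 (2.18) were higher through the male array alone, which lay 5.22 and 4.36 above the other strains while the female array lay 0.00 and 0.01 above. Without the male array their values were 0.00 (adjusted p = 1) and 0.01 (adjusted p = 0.998).

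In P/J the protease gene Klk8 was higher by 3.38, Gm13306 by 2.90 and Bcat2, an enzyme of branched-chain amino acid breakdown, by 2.41, while Rpn1 (-7.54), Ifi27l2a (-3.88) and the carrier gene Slc35e1 (-3.49) were lower. In 129S1/Sv1mJ Gdpd3 was higher by 3.89 and Bcat2 by 2.42, and Fam89a was lower (-2.77). Further calls in that strain were lost without 1 of its arrays: Cpne8 (2.57; adjusted p = 0.0832 without the female array), the splicing factor gene Rbfox2 (-2.95; adjusted p = 0.0968 without the female array) and the syndecan gene Sdc4 (-2.84; adjusted p = 0.163 without the male array). In c57BL/6J Rpgrip1 was higher by 3.89, Pttg1 by 3.79 and the zinc finger gene Zfp874a by 3.03, while Cap1 (-4.25), Anp32a (-4.21) and Tmem87a (-4.09) were lower. In RIIIS/J Gdpd3 was higher by 4.48, Rimklb by 3.91 and the scavenger receptor gene Stab2 by 3.58, while Ncmap (-6.87), Erdr1 (-5.12) and Plekhm3 (-4.46) were lower. The adjusted p of the calls in these 4 strains was at most 0.00321. A further probe set followed the strain means of Krt8 (r = 0.97), Pttg1 (r = 0.91) and Plekhm3 (r = 0.88), but not closely those of Slc35e1 (r = 0.35), Rbfox2 (r = 0.30), Anp32a (r = 0.17), Rimklb (r = -0.19) and Sdc4 (r = -0.42).

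Between the sexes, the largest differences were those of the sex chromosomes and of a few secretory genes. Xist was lower in males by 6.53 (-6.53, SE 0.34, 25 of 25 strains). Eif2s3y was higher in males by 3.77 (SE 0.17, 24 of 25 strains), and the Y chromosome genes Uty by 2.15 (SE 0.09) and Kdm5d by 1.78 (SE 0.08), each in 25 of 25. Lcn2, an iron-scavenging protein of neutrophils and epithelia, was higher in males by 3.12 (SE 0.38), the milk protein gene Csn3 by 3.06 (SE 0.55) and Wfdc18 by 3.04 (SE 0.37). All 3 had their highest strain mean in BTBT T+tf/J, but none was called for strain (limma F test, adjusted p = 0.4, 0.473 and 0.482). Their male and female values hardly correlated over strains (r = 0.11, -0.01 and -0.03).

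The sex test called 12779 of 22205 probe sets, 5232 higher in males and 7547 higher in females, with a median size of 0.30. The balance depended on the scaling of the arrays, with 5776 and 6838 after centring on array medians and 6277 and 6398 after quantile normalization. At 1 log2 unit or more there were 255, with 118 higher in males and 137 in females. The share called was similar for probe sets that did not pass the filter, at 48.4% (11058 of 22832), with a median size of 0.09. Since male and female arrays had separate floors of intensity, sex and processing cannot be told apart here.

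Other genes higher in males were the orphan receptor genes Gpr162 (1.91, SE 0.04) and Gpr153 (1.52, SE 0.03), Sdc4 (1.71, SE 0.23), Fam219a (1.67, SE 0.03), the linker histone gene H1f10 (1.45), Mxra7 (1.44) and the kinase gene Map3k11 (1.41). Lower in males were the neuronal secreted protein gene Lgi2 (-1.77, SE 0.08), the cilium gene B9d2 (-1.70), the DNA repair gene Shld2 (-1.48), Fcrls, a gene of resident macrophages (-1.45), the amino acid transporter gene Slc7a3 (-1.45), Bphl (-1.42), the retinol carrier gene Rbp4 (-1.38), the protease inhibitor gene Slpi (-1.37), Shisa3 (-1.36) and Rab29 (-1.33). Each had its sign in 24 or 25 of the 25 strains and an adjusted p of at most 3.15e-05. Gpr162, Gpr153, H1f10, B9d2, Shld2, Fcrls, Slc7a3, Slpi and Rab29 had means below 4, near the floor of the arrays.

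**Figure D3:**
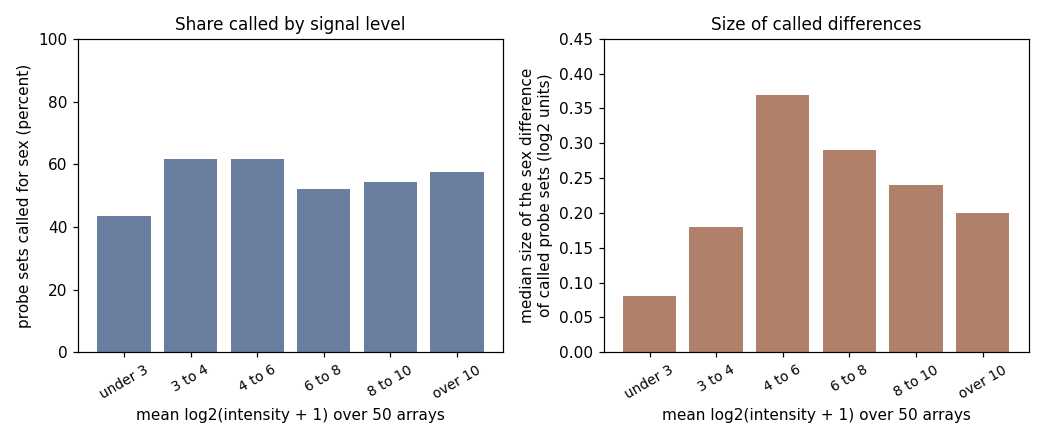
Left, the percentage of probe sets called for sex in classes of mean log2 intensity over 50 arrays, and right, the median size of the called differences in log2 units. The share called lies between 43.5% and 61.7% in every class.

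In the list of sex chromosome genes 8 of 8 tested members were called, 3 higher in males and 5 in females (8 adjusted over the list alone), the X-linked Kdm5c (-0.86), Kdm6a (-0.74), Eif2s3x (-0.69) and Ddx3x (-0.34) among them. Camera called 0 of 37 lists for sex, with 5 at an unadjusted p under 0.05 (lowest adjusted p = 0.334). With an estimated correlation it called 0, with 0 at an unadjusted p under 0.05 (lowest adjusted p = 0.978). Over all 11204 genes, 2762 were called higher in males and 3846 in females. Of lists picked after their values were seen, 7 of 9 fibroblast and matrix genes were called higher in females and 0 in males, with Pdgfra at -0.92 and Mgp at -0.54, and 8 of 18 potassium and HCN channel genes were called higher in males and 3 in females, with Kcns1 at 0.79 and Hcn2 at 0.55.

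The strain labels were checked by the similarity of arrays. For 40 of 50 arrays the closest array of the other sex was that of the same strain (19 male and 21 female arrays). Arrays of the same strain correlated at a mean of 0.48, from 0.14 in P/J to 0.69 in RIIIS/J, and arrays of different strains at -0.02 (permutation p = 1e-05). Strains that share a name stem were more alike than other pairs, with a mean r of 0.157 over 5 pairs against -0.044 over 295 (difference 0.201, permutation p = 0.00079). Within stems, C57BR/cdJ and C58/J correlated at 0.31 and c57BL/6J with C58/J at 0.01. The closest pair of all was CBA/J with C3H/HeJ at 0.40.

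**Figure D4:**
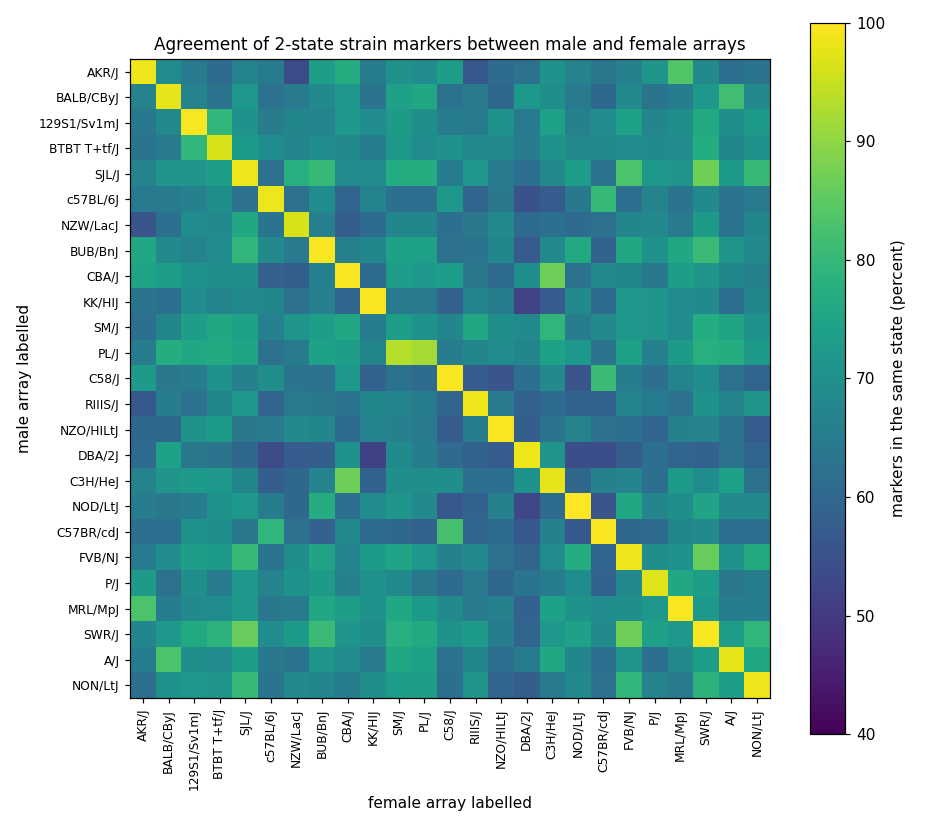
Percentage of 136 strain markers found in the same of 2 states, for each male array (vertical) against each female array (horizontal), with the label of each array on the axes. Pools of the same strain lie on the bright diagonal, except that the array labelled male SM/J matches no female array closely and the array labelled male PL/J matches the arrays labelled female SM/J and female PL/J. The markers were chosen in the 18 strains whose arrays were each other's closest. Agreement within those strains was therefore favoured by the choice and is no check of their labels.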

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

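The tests of a mislabelled sample, of RNA quality and of a mix of SM/J and PL/J, and the comparison without those strains, were chosen only after the result was seen; the other tests of this part were set before.

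Chrna6 differed between the pools of SM/J: the male array lay 2.03 above the mean of the other strains' males and the female array -0.78 relative to the other females. This difference between the sexes was not tested, since each is a single array. The control gene Gapdh had a 3' minus 5' signal above 0 in the male BTBT T+tf/J array (0.60) and the female P/J array (0.34) only, and those arrays were closest to each other among arrays of the other sex (r = 0.56). Xist was also above 5 in the male arrays of BTBT T+tf/J (7.78), SWR/J (6.73), NON/LtJ (5.42), NZW/LacJ (5.27) and NOD/LtJ (5.19), against a median of 2.94 in males other than PL/J.

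The arrays labelled male PL/J and female SM/J carried genes of both sexes. Eif2s3y in the array labelled female SM/J lay 3.74 above the median of the other females and Uty at 4.31 above every other female, though Kdm5d at 2.67 was at the female level, and Xist in the array labelled male PL/J 6.03 above the median of the other males, which argues against a plain mislabelling of samples of 1 strain and sex. Poor RNA is argued against for the array labelled female SM/J, whose Gapdh signal of -0.54 was near the female mean of -0.528, and stays open for the array labelled male PL/J, whose -0.31 was the second highest of the males although inside the range of the other strains (-0.73 to 0.60), a weak bound that the male BTBT T+tf/J array sets. A mix of strains failed both of its tests, since the largest weight of a strain had to lie below that of every array of the other strains: fitted by the arrays of the other sex the smaller largest weight was 70.4% against a lowest of 59.2%, and fitted without each other the female SM/J array had 63.6% against 59.9%, while the male PL/J array, with 52.7%, met the bound. These bounds are weak, because in the first fit each doubtful array was explained mostly by the other. The 59.9% is that of the male SWR/J array, which has raised Xist itself. In the second fit both arrays took 20.8% and 19.7% of SM/J, and 52.7% and 63.6% of PL/J. In the 46 arrays of other strains these shares were at most 14% and 12.4%. The leading Chrna6 probe set lay at 7.77 in male PL/J and 6.84 in female SM/J. These values lie between those of the arrays labelled male SM/J (9.67) and female PL/J (4.79). The second probe set, 9.66 and 3.94 in those arrays, was only 3.48 and 3.89 in the doubtful ones. The probe sets point different ways, so that the source remains unexplained.

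Between the sexes, 12779 probe sets were called, and in 100 swaps of sex within strains 1, the real one, gave as many (highest other 3218), so chance can be excluded. Separate normalization of male and female arrays is a candidate explanation for most of these calls, since 48.4% of probe sets under the filter, which lie at the floor, were called too. A difference in transcripts beyond the sex chromosomes stays open: called probe sets above a log2 of 8 had a median change of 0.23 against 0.09 under the filter, larger as it would need to be, but a set of arrays normalized apart could give the same. Sex and processing cannot be told apart, because the floor of intensity divides the arrays exactly by sex, and no label records how they were normalized.

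Between strains, 5475 probe sets were called, and of 100 re-matchings of the female strain labels 1, the real one, gave as many (highest other 533); for single strains, 6335 calls were likewise reached by 1 of 100 (highest other 1562), so chance can be excluded for both. A strain variant under the probes, which changes binding and not the transcript, would leave the gene's next probe set unmoved unless that set covers the variant too. The median correlation over strains with the next probe set was 0.53 in 1317 called genes and 0.30 in 3731 others. It was higher by 0.23, the side that the test had set against variants under probes. This does not settle the general cause, because called genes were chosen for their variation between strains and 1 variant can lie under both probe sets. For single genes such variants stay open as well. Of 67 called genes with a range of at least 3, 46 had a correlation above 0.5, and Anp32a (0.17), Rimklb (-0.19) and Galc (-0.63, chosen after its value was seen) did not. With smaller ranges, Scn2b had 0.05 and Cacna2d2 0.13. A difference in transcript level between strains remains untested by another method.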

How the results depend on the processing

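The comparisons without SM/J and PL/J, without the 2 arrays with the highest Gapdh signal, and within the strains below the 6 highest in Chrna6 were chosen only after the result was seen; the other tests were set before. Counts that stayed within 1.5 times are not listed. With 1 probe set per gene, strain differences numbered 3139, those of 2-fold or more 2199 and single-strain calls 2417, since fewer features were tested; without a sex term the first 2 were 2752 and 2465; with 16 added before the log, single-strain calls were 3492. The cause was not tested for the last 3. For sex, 23777 probe sets were called with no filter (11054 higher in males, 12723 in females), 8017 with a filter at log2 6 (3138 and 4879), 6663 with 1 per gene (2789 and 3874) and 255 at 1 log2 unit or more (118 and 137), as more or fewer were tested or allowed. Without the strain block, sex calls were 11125, within 1.5 times, and camera called 0 lists; the block changed no other call. Leaving out each array gave 4805 to 8304 strain differences, 3847 to 6545 of 2-fold or more, 6076 to 8447 single-strain calls, a Chrna6 range of 2.96 to 4.70, called each time, and 12416 to 13048 sex calls; the lone array left is assumed to vary like the others. Of 10 receptor genes, 0 correlated with Chrna6 in males only, with the other Chrna6 probe set or within the lower strains, and 0 to 1 without each strain. The cause was not tested. Other probe sets were tested for P2rx3, P2rx4, P2rx6, P2rx7 and Chrna3 only, and 0 correlated with Chrna6. P2rx2 is not among them, so that setting cannot bear on its call. The count of genes correlated with Chrna6 was 0 (limma; 1409 at an unadjusted p under 0.05 at first) in every alternative. Gene lists called by strain numbered 15 to 25. Of 2126 results for 155 named genes and correlations under alternatives, 2039 kept direction and side of the threshold, 87 lost the call and 0 reversed. In these counts the runs without each array or strain enter only by their lowest and highest value. Losses without single arrays are therefore understated, such as those of Col1a1 (35), Gal (33) and Npy2r (32). The sex changes of all 24 named results kept theirs. Signal over background limits P2rx2, Chrnb3 and other genes near log2 4, where the floor hides differences.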

Other observations

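The hepatocyte test was set before its result was computed, but Alb, Ttr, Serpina1c and Fabp1 had been seen high before its list was written and before its bounds were set for DBA/2J alone instead of 4 strains; all figures given here for genes outside the fixed naming rule were chosen only after the result was seen.

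Some glial, vascular and connective tissue genes also differed between strains, though of these lists only that of fibroblast and matrix genes passed Fisher's exact test, and the Schwann cell and endothelial lists had 25% called, near the 26.1% of all genes. In the satellite glia list 4 of 8 tested members were called (5 adjusted over the list alone; male to female r of list means 0.57, rho = 0.59), with the gap junction gene Gja1 ranging by 1.46, the potassium channel gene Kcnj10 by 1.30 and glutamine synthetase (Glul) by 1.23. In the myelinating Schwann cell list 2 of 8 were called (3 over the list alone), Ncmap and Pmp22, the latter ranging by 0.51; the list's r of 0.69 rests on RIIIS/J and SJL/J (0.07 without them, rho = 0.11). Mural cell markers had 3 of 4 called (4 over the list alone; r = 0.78, rho = 0.82), with Rgs5 ranging by 3.11 from MRL/MpJ to CBA/J, Pdgfrb by 1.27, and Myh11 by 1.33 but not called without the male AKR/J array (adjusted p = 0.0743). Endothelial markers had 2 of 8 (2 over the list alone; r = 0.31, rho = 0.25, not called), Cldn5 and Esam, the latter ranging by 0.81 but not called without any of 4 single arrays (adjusted p 0.0522 to 0.0895). Fibroblast and matrix genes had 7 of 9 (9 over the list alone; Fisher's adjusted p = 0.0097; r = 0.47, rho = 0.41; 0.38 without the 2 farthest strains, not called), with Postn ranging by 2.65, Mgp by 1.98, and Col1a1 by 1.92 but not called without any of 35 single arrays (0.0507 to 0.0814). Cholesterol synthesis genes had 7 of 9 (7 over the list alone; 0.0097; r = 0.76, rho = 0.73, 0.73 without the 2 farthest strains), with Insig1 ranging by 1.63, Lss by 1.38 and Dhcr7 by 1.18.

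Other lists held markers of blood, adjacent tissues and physiological state. Bone marrow granulocyte markers had 4 of 6 called (4 adjusted over the list alone), with S100a9, S100a8 and Ngp all highest in C3H/HeJ and ranging by 5.17, 4.53 and 4.18; the list's r of 0.50 fell to 0.31 without C3H/HeJ and BUB/BnJ. Erythrocyte markers had 3 of 3 (3 over the list alone; r = 0.62, rho = 0.66), with Slc4a1 ranging by 2.01, Hbb-b2 by 1.68, and Alas2 by 2.35 but not called without the female NON/LtJ array (adjusted p = 0.0579). Cartilage and bone markers had 2 of 2 (2 over the list alone; r = 0.75, rho = 0.76), Comp ranging by 2.12 and Ibsp by 1.27. Spinal cord markers had 1 of 3 (1 over the list alone; r = -0.01), Aqp4 ranging by 2.30. Skeletal muscle markers, adipocyte markers, lymphocyte markers and sex chromosome genes had 0 of 10, 0 of 2, 0 of 4 and 0 of 8 called by the limma F test over all genes and over each list alone (r = -0.08, 0.09, -0.15 and -0.01); the muscle list was highest in SM/J, at 1.35 in the male and 3.93 in the array labelled female SM/J relative to the mean of all arrays. Nerve injury genes had 4 of 10 (5 over the list alone; r = 0.42, rho = 0.65); single male arrays stood apart, with list means of 2.05 in male and 0.02 in female SJL/J and 1.15 in male P/J, and Sprr1a at 8.07 in male and 2.76 in female SJL/J. Of these genes Bdnf ranged by 1.71, and Csf1 by 1.19 but not called without any of 24 single arrays (0.0501 to 0.243). Immediate early genes had 1 of 8 (1 over the list alone; r = 0.29), Egr3 ranging by 2.11, heat shock genes 2 of 7 (2 over the list alone; r = 0.30), with Hspa1b ranging by 2.04 and Hspa1a by 2.72 but not called without any of 7 single arrays (0.052 to 0.148), and circadian clock genes 1 of 10 (1 over the list alone; r = 0.17), Dbp ranging by 2.13. The male to female r of the P2X list was 0.11, of the nicotinic list 0.46 (rho = 0.58), of the chromosome 8 list 0.28 (rho = 0.51) and of the known strain variants 0.49 (rho = 0.56). Of 37 lists, r was called in 22, rho in 20, and r without the 2 farthest strains in 18, with 17 called in all 3.

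Dysf, the muscle membrane repair gene dysferlin, was lower in A/J than in the other strains (-4.43, adjusted p = 1.03e-12; -4.42 in the male and -4.43 in the female array). Tyrp1, a melanin synthesis gene, was lower in NZO/HILtJ (-3.04, adjusted p = 5.32e-09) and in SM/J (-2.77, adjusted p = 3.32e-08).

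Alb, Ttr and Serpina1c lay high in both arrays of DBA/2J, and also in C58/J, FVB/NJ and C3H/HeJ (Alb at 7.59, 7.50 and 6.96). RNA from liver cells is a candidate source. Of 17 other abundant liver transcripts with a probe set, 9 (52.9%) were at least 1 log2 unit higher in DBA/2J, between the 80% set as the mark for liver RNA and the 50% below which it was to be ruled out, and 8 of 16 (50%) without Fabp1, so the test decides nothing. Of the 17, Fabp1 was 8.79 against 4.34 in the other strains and Apoa2 6.60 against 3.03, while Apoh (0.88), Ahsg (0.84), Cps1 (0.81), Ambp (0.77), Apoc1 (0.77), Apoc3 (0.59), Hp (0.40) and Tat (0.09) were higher by less than 1; a liver source and expression in the ganglion cannot be told apart with these values.

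With Chrna6 as covariate limma called 0 probe sets, with 1409 at an unadjusted p under 0.05. A count of 0 is reached by any order of the strain means, here by 100 of 100 permutations, so that comparison decides nothing about chance. The highest of the other permutations called 1423 probe sets at an adjusted p under 0.05 (the cause was not tested). Without SM/J and PL/J the strongest relations were those of Chia1 (r = -0.68, p = 0.000158), Niban3 (r = 0.68), Kat6a (r = -0.68), Sulf1 (r = -0.64) and Mrap2 (r = 0.64), none called (adjusted p = 0.875).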
